A study of Rattus norvegicus with 18 samples.

How the data were processed

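Gene expression was measured on 18 Affymetrix arrays, an RAE230A (chip A) and an RAE230B (chip B) array for each of 9 single-cell-derived colonies of fetal rat calvaria cells. Per the labels, cells were sorted singly by flow cytometry and grown for 4 weeks at 37 C in 5% CO2 in medium with fetal bovine serum, ascorbic acid and the additives abbreviated BGP and Dex. RNA was prepared from 100 to 300 cells per colony and amplified with a small-sample labelling protocol. The deposited values are MAS5 signal intensities per probe set on a linear scale, per the submitters' processing notes and the file headers; the MAS5 version is not given in the sources used here. The submitters sorted the colonies into 3 types by marker expression, and the labels give 3 colonies (I, II and III) for each of osteocalcin alone, osteocalcin and adipsin together ("both" below) and neither marker ("neither"). Each colony grew from its own cell, so p-values measure the spread between colonies. Limma, used below, moderates that spread toward the spread of probe sets of like intensity. Whether the colonies of a type came from separate cell preparations is not given in the sources used here.

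The 2%-trimmed mean signal was 1500 on every deposited array except the chip A array of osteocalcin I, where it was 64.4. Per the deposited array records, that array was also hybridized on another day than the other chip A arrays. After this was seen, all arrays were rescaled to a trimmed mean of 1500, which departs from the planned use of the signals as deposited. Signals as deposited, and a fit without that array, were run as alternatives added after seeing the data. Signals were taken as log2(signal + pseudocount). The pseudocount was the median over the 9 arrays of each array's 25th percentile, 238.7 on chip A and 336.2 on chip B. A log2 difference on this scale understates the change of dim probe sets.

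Of 15923 probe sets on chip A and 15333 on chip B, 57 control probe sets per chip were left out. A probe set was kept if its signal exceeded the array median on at least 3 of the 9 arrays, which left 9425 and 9887. The 2 marker genes, Bglap (osteocalcin) and Cfd (adipsin), were exempt from the filter and brought the number tested to 19314. Names came from the platform annotation. On chip A 12789 probe sets had 1 gene symbol, 312 several and 2822 none; on chip B 7570 had 1, 100 several and 7663 none. No gene was named from a probe set with several symbols. Gene identifiers of 12754 and 7530 single-symbol probe sets were found in the RefSeq gene table, and 0 symbols needed updating.

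Each chip was fitted alone with limma 3.58.1 in R 4.3.3 (3 group means over 9 arrays, 6 residual degrees of freedom, empirical Bayes with an intensity trend, two-sided moderated tests). The p-values of both chips were adjusted together by the Benjamini-Hochberg method for each comparison, and an adjusted p under 0.05 counted as a call. Gene lists were tested with limma's cameraPR at a preset inter-gene correlation of 0.01, on 1 probe set per gene (chip A before chip B, then the highest mean signal), with adjustment over the 15 lists of a comparison. An estimated correlation (camera), the rotation test fry and the mean statistic of all probe sets of a gene were run beside it. The lists were osteoblast, adipocyte, collagen and matrix, chondrocyte, smooth and skeletal muscle, endothelial, macrophage and osteoclast, cell cycle, oxidative phosphorylation, ribosomal proteins, glucocorticoid response, BMP, TGF-beta and Wnt targets, stress and immediate early, cholesterol synthesis, and interferon response.

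The named genes were, per comparison, up to 10 genes higher and 10 lower with the smallest p among probe sets with 1 symbol whose groups did not overlap, then Bglap and Cfd, and then up to 3 members of each list with the smallest p. The groups, tests, lists, naming rule and all settings but those added later were fixed before the data were examined. Genes named outside the rule are said to be so where they appear. With 3 colonies against 3, an exact permutation test cannot give a p under 0.1.

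Colony profiles were compared by Pearson's r over the kept probe sets, and mean r within and between types was tested by one-sided exact permutation over all 280 partitions of 9 colonies into 3 groups of 3. As a check of sample identity, each chip A array was matched to the chip B arrays over the 100 probe sets present on both chips, after centring each probe set. Of the 9 chip A arrays, 8 matched the chip B array of their own colony best; osteocalcin III matched both III (r = 0.551) better than its own colony (r = 0.403). Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

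The steps were tested on simulated data. In 10 simulations of both against osteocalcin (19312 probe sets, 200 changed in each), 2.84% of probe sets changed by 1 log2 unit were called, 41.5% of those changed by 2 and 87.3% of those changed by 3, and 6.53% of all calls were false. In 20 simulations without change on 10080 genes, 3 of 900 list tests were called. With the collagen and matrix list shifted by 1 log2 unit, its adjusted p was 2.75e-31 with the preset correlation and 0.000219 with the estimated one. The simulated noise was drawn independently for each probe set, so genes of a list were not correlated. In the colonies the estimated correlation was 0.203 for the collagen and matrix list and 0.481 for the muscle list. The simulations therefore do not show how often lists of correlated genes are called falsely.

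The alternatives covered the pseudocount, the filter, quantile normalization, the variance model, array weights, a fit of only the 2 groups compared, the replicate number as a block, fluidics station and chip lot as blocks, the 3' to 5' ratio of Gapdh and Actb as a covariate, adjustment within each chip, the list tests above, and each colony left out in turn. The ratio covariate was the mean of the Gapdh and Actb log2 ratios. On chip A it partly marked colony neither II, where Gapdh itself was very low. Its Gapdh ratio was 1.06, against 3.11 or more in the others, while its Actb ratio of 3.55 lay among theirs (2.51 to 3.87). On chip A, station 1 held the 3 osteocalcin colonies with both I and both II, and station 2 held both III with the 3 neither colonies. On chip B, station 1 held the 3 both colonies with neither I, and station 2 held the 3 osteocalcin colonies with neither II and neither III, so both and osteocalcin colonies shared no station there. Also on chip B, the 3 osteocalcin arrays were run before all others, so on that chip run and type cannot be told apart in the comparisons with osteocalcin. All chip A arrays came from 1 chip lot, so the lot block changed nothing there. On chip B the neither colonies shared a lot with osteocalcin I, and both I shared one with osteocalcin II and III. Both II and both III were each alone in a lot and did not count there under the block. Both and neither colonies thus shared no lot on chip B.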

Results

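Transcript levels were measured in 9 colonies, each grown from a single fetal rat calvaria cell, a bone-forming cell population of the skull. The colonies had been typed by the submitters from marker expression: osteocalcin, a bone matrix protein of mature osteoblasts, and adipsin, a protease secreted by adipocytes. The series title names adipocyte and bone markers, and the 3 comparisons ask which other transcripts differ between colonies with osteocalcin alone, with both markers and with neither marker (n = 3 colonies each). Every colony was read on chip A and chip B. The number of arrays limits the precision: the median standard error of a difference between 2 types was 0.497 log2 units. The 10 brightest probe sets held 2.78% to 7.29% of the signal on chip A and 1.43% to 4.49% on chip B.

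The marker transcripts served as a check of the labels and are no independent finding, because the colonies were sorted by them. Bglap, which encodes osteocalcin, was dim in all 9 colonies (signals from 20.9 to 299). Its log2 level was 8.15 ± 0.084 (SD, n = 3) in osteocalcin colonies, 8.06 ± 0.075 in both colonies and 8.48 ± 0.52 in neither colonies. The highest value belonged to a neither colony, neither III, at the 22.3 percentile of its array; in the other 8 colonies it lay between the 1.28 and 5.39 percentiles. In limma's test osteocalcin differed from neither by -0.33 (SE 1.05, adjusted p = 0.959) and both from neither by -0.41 (SE 1.05, adjusted p = 0.906), so the array did not separate the types by this transcript. These differences were -0.03 and -0.12 without neither III and -1.09 and -1.75 with no pseudocount. Cfd, which encodes adipsin, was 9.29 ± 0.32 in both colonies, 8.74 ± 0.19 in osteocalcin colonies and 8.86 ± 0.35 in neither colonies (SD, n = 3 each). The 3 both colonies lay above the 3 osteocalcin colonies, by 0.54 (SE 0.628, adjusted p = 1 by limma), and overlapped the neither colonies, from which they differed by 0.42 (SE 0.628, adjusted p = 0.829). Over 24 other settings these differences ran from 0.34 with array weights to 1.02 with no pseudocount and from 0.22 without neither I to 0.82 with no pseudocount. For both markers limma's SE lay above the SD of every type. Limma moderated their spread toward that of probe sets of like intensity, with 6.79 prior against 6 residual degrees of freedom. Their p-values therefore do not measure the spread between colonies alone.

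**Figure D1:**
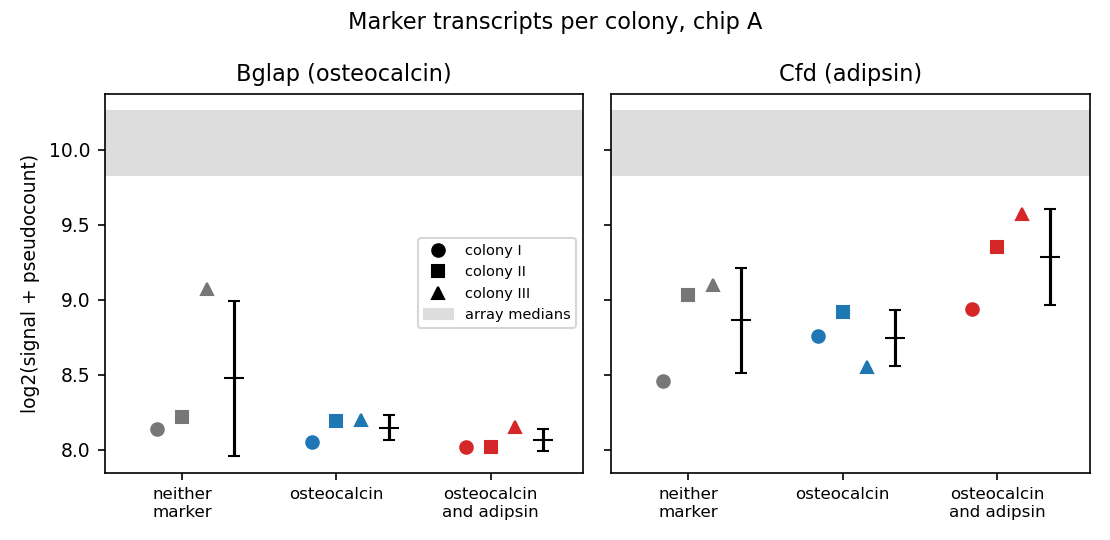
Log2(signal + pseudocount) of Bglap and Cfd on chip A in each colony; crosses with bars give the mean ± SD of 3 colonies, and the grey band spans the medians of the 9 arrays. Bglap lies far below the array medians in all 9 colonies and is highest in neither III, while Cfd is highest in both III at 9.57.

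Colonies of one type were not shown to resemble each other more than colonies of different types. On chip A the mean correlation was 0.785 ± 0.0977 (SD, 9 pairs) within types and 0.779 ± 0.0796 (27 pairs) between types (exact one-sided permutation p = 0.318). On chip B it was 0.566 ± 0.151 within and 0.536 ± 0.132 between (exact one-sided permutation p = 0.0929). Type accounted for 27% of the variance on chip A, against a median of 23.9% over all partitions, and for 29.1% against 24.3% on chip B. Osteocalcin colonies (mean r 0.856 on chip A, 0.635 on chip B) and both colonies (0.822 and 0.665) were more alike among themselves than neither colonies (0.678 and 0.398), an order that was not tested. Neither III had the lowest mean correlation with the other 8 colonies on both chips, 0.664 and 0.326, where the next lowest were 0.755 and 0.513.

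**Figure D2:**
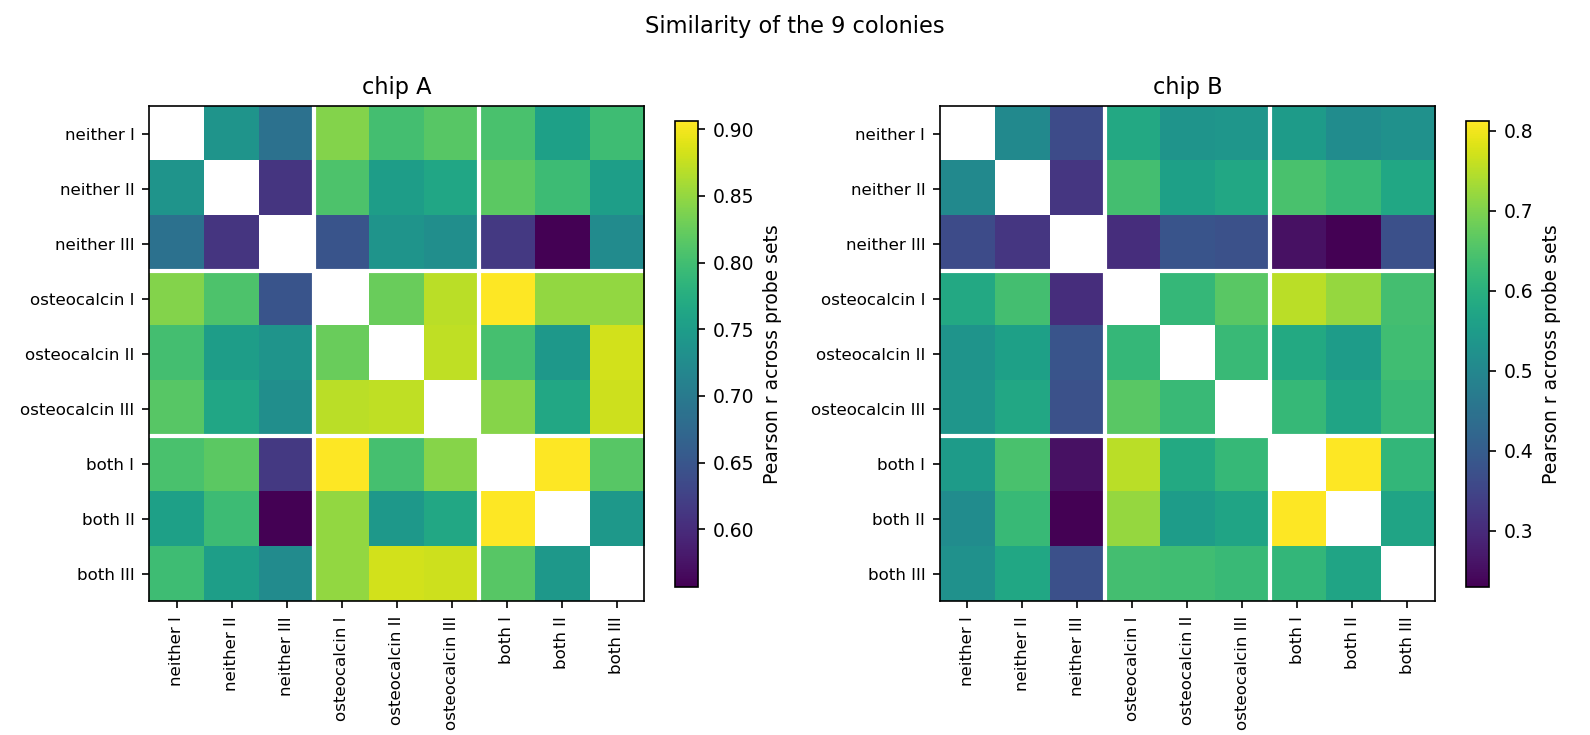
Pearson correlation of log2 signals between each pair of colonies over the kept probe sets of chip A and of chip B; white lines separate the 3 types. Neither III has the lowest correlations on both chips, and both I with both II is the highest pair on chip B at 0.812.

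The comparison of both colonies with osteocalcin colonies asks what accompanies adipsin. Among genes whose groups did not overlap, Ackr4, a scavenging receptor for chemokines, had the smallest p. Its level was 13.51 ± 0.206 in both colonies and 9.93 ± 1.29 in osteocalcin colonies (SD, n = 3 each), a difference of 3.59 log2 units (12-fold, SE 0.576) that did not pass limma's test (adjusted p = 0.0804). Ackr4 was read on chip B, where all both colonies ran on fluidics station 1 and all osteocalcin colonies on station 2. Gda, guanine deaminase, was higher by 2.58 (SE 0.513, adjusted p = 1) and Acad11, an acyl-CoA dehydrogenase, by 2.58 (SE 0.509, adjusted p = 0.587). The complement protease C1r was higher by 2.77, Ccn5 by 1.61, Ppfibp2 by 1.63, Kazald1 by 1.40, Olfml3 by 1.28, the class I histocompatibility gene RT1-CE16 by 1.67 and Car11 by 1.54, although 1 of its 2 other probe sets pointed the other way. On the lower side were Septin4 (-1.88), Cd200 (-1.86), the chemokine Ccl21 (-1.99), Wnt2 (-1.76), Pinlyp (-1.72), Iffo2 (-1.78), Lrrc8c (-1.69), Sorbs2 (-1.23), Tmem88 (-1.20) and Gmfb (-1.52, with 1 of its 2 other probe sets opposite). All of these genes had 3 colonies of one type above 3 of the other and an adjusted p of 1 by limma, except Ackr4 and Acad11.

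Limma called 0 of 19314 probe sets in this comparison; 654 had an unadjusted p under 0.05 (347 higher, 307 lower), where chance gives 966. With array weights, under which arrays count unequally, 88 were called, and Ackr4 passed in 4 of 24 other settings. Groups did not overlap for 10.1% of probe sets, where chance gives 10%.

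Of the 15 gene lists, 7 were called by cameraPR with the preset correlation, and 0 with an estimated correlation or by fry. Below, rose and fell compare group means, and colony both III did not follow each of these directions. The collagen and matrix list rose in both colonies (median +0.38, 30 of 43 members higher, adjusted p = 0.000109 by cameraPR; adjusted p = 0.60 with an estimated correlation). Its members with the smallest p were Col6a3 (+2.19, SE 0.691) and the laminin chains Lamb1 (+1.63) and Lamc1 (+0.76). The smooth and skeletal muscle list fell (median -0.94, 14 of 15 members lower, adjusted p = 0.000301; adjusted p = 0.60 with an estimated correlation). The smooth muscle myosin Myh11 differed by -2.09 (SE 0.731), the actin-binding proteins Cnn1 by -1.54 and Tagln by -1.37. Oxidative phosphorylation genes fell (median -0.28, 38 of 47 lower, adjusted p = 0.000485; adjusted p = 0.60 with an estimated correlation), with Cox5a at -0.97 and Atp5f1e at -0.84. Ribosomal protein genes fell (median -0.19, 33 of 40 lower, adjusted p = 0.0357; adjusted p = 0.698 with an estimated correlation), but the call held in 15 of 26 alternatives and was lost with quantile normalization (median +0.0079, adjusted p = 0.826) and with either other filter (adjusted p = 0.128 and 0.0532); over the alternatives the adjusted p ran from 0.000605 to 0.826. Stress and immediate early genes fell (median -0.28, 16 of 21 lower, adjusted p = 0.0256; adjusted p = 0.60 with an estimated correlation), among them Ier3 at -1.45 and Gadd45g at -1.19, with Egr1 at +0.87. The cell cycle list rose (median +0.32, 19 of 25 higher, adjusted p = 0.0143; adjusted p = 0.673 with an estimated correlation): Prc1 differed by +2.17 and Nusap1 by +1.53, both acting on the mitotic spindle, and the replication inhibitor Gmnn by -1.36. The interferon response list rose (median +0.30, 13 of 17 higher, adjusted p = 0.0073; adjusted p = 0.268 with an estimated correlation). Isg15, an interferon-induced modifier (+1.78, SE 0.567), and Psmb8, an immunoproteasome subunit (+1.32, SE 0.381), were the 2 members that passed limma's test when adjusted over the list alone (adjusted p = 0.0495 for each); 0 members of any list passed when adjusted over all genes tested. The other lists were called in 24 (collagen and matrix), 22 (muscle), 22 (oxidative phosphorylation), 19 (stress), 19 (cell cycle) and 16 (interferon) of 26 alternatives. All alternatives except the estimated correlation and fry kept the preset correlation of 0.01, so these counts do not test it. Estimated correlations were 0.203 (collagen and matrix), 0.481 (muscle), 0.293 (oxidative phosphorylation) and 0.45 (ribosomal proteins). They were 0.183 for stress, 0.319 for cell cycle and -0.0118 for interferon genes.

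The lists of the lineages that the markers stand for were not called. In every comparison they count Bglap (osteoblast) and Cfd (adipocyte), the markers by which the colonies were typed. Of 15 osteoblast genes 7 were higher and 8 lower (adjusted p = 0.872), with Enpp1 at -1.94 (SE 0.752), Col1a2 at +1.34 and Cdh11 at +0.78 (1 of its 2 other probe sets opposite). Of 26 adipocyte genes 11 were higher and 15 lower (adjusted p = 0.872), with the lipid droplet protein Plin2 at +0.57 (SE 0.42), the glucose transporter Slc2a4 at -0.68 and Dgat2 at -0.41. Glucocorticoid response genes had a median of +0.47 (10 of 13 higher, adjusted p = 0.141), with Mt2A at +1.91 and Fkbp5 at +0.83 (its other probe set opposite). Among BMP, TGF-beta and Wnt targets (median -0.02, 14 of 30 higher, adjusted p = 0.438) stood Id1 at -1.20, Tgfbi at -1.07 and the secreted Wnt binder Sfrp2 at +2.09. The chondrocyte (median -0.12), endothelial (-0.0034), macrophage and osteoclast (-0.16) and cholesterol synthesis (-0.13) lists had adjusted p of 0.71, 0.872, 0.568 and 0.568. The osteoblast list had a median of -0.03 against a mean of +0.03, and the endothelial test statistic pointed up while its median and mean were negative.

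With fluidics station as a block, a term that on chip B could be set only by neither colonies, 6 lists were called and 0 probe sets: the median was +0.75 for collagen and matrix and -1.49 for muscle, and the interferon list lost its call. On chip A that term could be set only by the both colonies. There both III no longer counted, and the block compared both I and both II with the osteocalcin colonies. The values within station 1 rest on these same colonies and are not separate evidence. Within station 1 of chip A, both I and both II differed from the 3 osteocalcin colonies by +0.75 in the collagen and matrix list (34 of 41 higher), -1.63 in muscle, -0.55 in oxidative phosphorylation, -0.40 in ribosomal proteins, -0.52 in stress, +0.60 in cell cycle and +0.26 in interferon genes. There limma called 38 probe sets, 34 of them higher, including the secreted phospholipase Pla2g2a (+6.50, adjusted p = 2.29e-05) and the matrix proteoglycan genes Dcn (+3.72, adjusted p = 0.00216) and Fmod (+3.48, adjusted p = 0.00216); these 3 were chosen after their values were seen. That fit left out both III, in which Pla2g2a, Dcn and Fmod were at 8.12, 9.80 and 10.08, no higher than the highest osteocalcin colony, while neither II had 11.75, 13.11 and 13.12; over both chips, 0 probe sets were called without both III. Both III did not share several list directions. Its mean over the oxidative phosphorylation list was 13.6, above the osteocalcin colonies (13.2, 13.43 and 13.42). For collagen and matrix it was 12.42, against 12.9, 12.42 and 12.73, and for cell cycle 9.938, against 9.897, 10.35 and 10.16. In the interferon list the both colonies (11.13, 11.37 and 11.04) all lay above the osteocalcin colonies (10.77, 10.94 and 10.74). The list calls rested largely on colony both II, without which the collagen and matrix list alone was called (median +0.34) and the cell cycle median was -0.09. Without that colony Sfrp2 stood at +0.89, Enpp1 at -0.92, Cdh11 at -0.0025, Dgat2 at -0.20, Tagln at -0.32, Cnn1 at -0.94, Prc1 at +1.38, Atp5f1e at -0.50, Ier3 at -0.52 and Gadd45g at -0.69. Without osteocalcin III Lamb1 stood at +0.86, Myh11 at -1.22, Fkbp5 at +0.49 and Egr1 at +0.53, without osteocalcin II Col1a2 at +0.85, without both I Slc2a4 at -0.42 and without both III Plin2 at +0.15. Without osteocalcin I 4 lists were called. With its chip A array at the deposited scale, as originally planned, 1 list and 1 probe set were called, while the median chip A difference moved to +0.86.

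**Figure D3:**
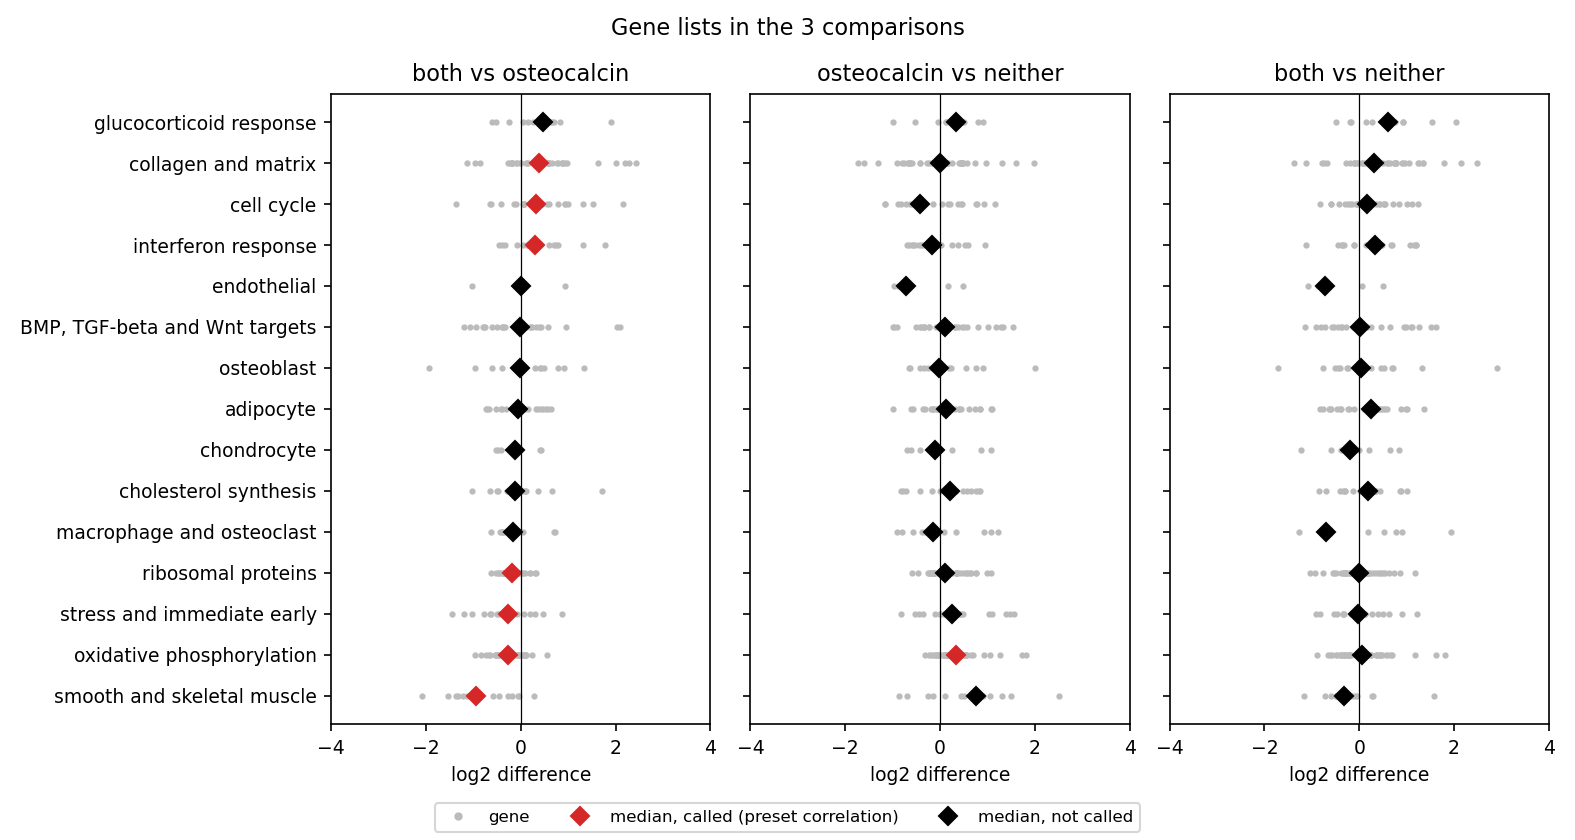
Log2 differences of the measured members of 15 gene lists (grey points) and list medians (diamonds) in the 3 comparisons; red diamonds passed cameraPR with the preset correlation. The call is shown in 7 lists for both against osteocalcin, in 1 list for osteocalcin against neither and in 0 for both against neither; 0 lists passed with an estimated correlation.

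The comparison of osteocalcin colonies with neither colonies asks what accompanies osteocalcin alone. Its osteocalcin values are those of the first comparison. Genes and lists that recur with the opposite sign, such as Ppfibp2, RT1-CE16 and oxidative phosphorylation, are therefore not separate evidence. Between both and neither colonies the oxidative phosphorylation median was only +0.07 (adjusted p = 0.872 by cameraPR). Higher in osteocalcin colonies were Mmp23, a metalloprotease (+2.45, SE 0.444, adjusted p = 0.327, with 1 of its 2 other probe sets opposite), and Lpcat3, a phospholipid-remodelling acyltransferase (+1.94, SE 0.325, adjusted p = 0.327). The mitochondrial thiolase Acat1 was 11.28 ± 0.45 against 9.44 (+1.84, SE 0.329, adjusted p = 0.335), and the cysteine protease inhibitor Cst3 was higher by 1.73 (SE 0.372, adjusted p = 0.611). The others on that side were Mzt2b (+2.29), Fkbp2 (+2.29), Chmp4c (+1.85), Fxr2 (+1.80), Ppp6r1 (+1.71, its other probe set opposite) and Pold4 (+1.68). Lower were the cytokine receptor Cntfr (-1.96, SE 0.452), the lectin Mbl2 (-2.06), the chemokine Cxcl3 (-1.84), Ppfibp2 (-1.58), RT1-CE16 (-1.62), Cdc26 (-1.56), Marchf9 (-1.94) and LOC102554253 (-2.04), each with an adjusted p of 0.611. Tmem131 (-2.18) and Rbbp6 (-2.01) were lower on the probe set with the smallest p, while for each gene 2 other probe sets went the other way.

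Limma called 0 of 19314 probe sets here; 1450 had an unadjusted p under 0.05 (798 higher, 652 lower; chance 966), and groups did not overlap for 12.2% (chance 10%). Oxidative phosphorylation was the 1 list called: it rose in osteocalcin colonies (median +0.33, 38 of 47 higher, adjusted p = 0.0103; adjusted p = 0.854 with an estimated correlation). The complex I subunit Ndufv1 differed by +1.81 (SE 0.401) and was the 1 member that passed limma's test when adjusted over the list alone (adjusted p = 0.028), against 0 over all genes tested; Ndufv2 stood at +1.72 and Sdhb at +1.27, but at +0.79 and +0.68 without neither II, where Ndufv2 was over 2 log2 units below all other colonies. The osteoblast list had 7 of 15 members higher (adjusted p = 0.793), with the secreted proteins Cthrc1 at +2.0 (SE 0.906) and Sparc at +0.91 (its other probe set opposite; +0.49 without neither III). Adipocyte genes split 15 to 11 (adjusted p = 0.789), with the lipase Pnpla2 at +1.10, Dgat1 at +1.09 and the glycerol channel Aqp7 at -0.99. The collagen and matrix list was even (22 of 43 higher, median +0.0054, mean -0.02, adjusted p = 0.698), with Bgn at +1.61 (+1.05 without neither III) and Fbln1 at -1.73. Muscle genes had a median of +0.75 (11 of 15 higher, adjusted p = 0.507) and ribosomal protein genes +0.10 (adjusted p = 0.507), while the endothelial list stood at -0.72 (4 of 6 lower, adjusted p = 0.267). The remaining lists had adjusted p between 0.507 and 0.968; in the osteoblast, chondrocyte, and macrophage and osteoclast lists median and mean differed in sign.

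No station of chip A held both osteocalcin and neither colonies. With station as a block, a term that on chip A could be set only by both colonies, 5 lists were called: oxidative phosphorylation (+1.06), ribosomal proteins (+0.71), muscle (+2.03), collagen and matrix (-0.83) and cell cycle (-0.43); within station 2 of chip B, limma called 0 probe sets (713 at an unadjusted p under 0.05). The oxidative phosphorylation call was lost with quantile normalization (median +0.10, adjusted p = 0.627). It was also lost, with medians of +0.34 with the stricter filter (adjusted p = 0.312), +0.36 with the 3' to 5' ratio as a covariate (adjusted p = 0.058), +0.23 without osteocalcin II (adjusted p = 0.0954) and +0.22 without neither I (adjusted p = 0.345). With the deposited scale of osteocalcin I, as originally planned, its median was -0.97 and 0 lists were called; over 26 alternatives its adjusted p ran from 4.43e-10 to 0.854.

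Both colonies were then compared with neither colonies, the pair of types that differ in both markers. Ackr4 was again far higher (13.51 ± 0.206 against 10.08, +3.44, SE 0.576, adjusted p = 0.159), as were Gda (+3.20, SE 0.513, adjusted p = 0.159) and Cped1 (+2.76, SE 0.491, adjusted p = 0.159). Cst3 was higher by 2.12 (SE 0.372, adjusted p = 0.177), Acat1 by 1.88 and the collagen-degrading protease Ctsk by 1.95 (SE 0.356, adjusted p = 0.177). Gstm4, a glutathione transferase, was higher by 2.36 and the pyrophosphate transport gene Ankh by 2.45, although 1 of its 2 other probe sets was opposite; Ppp6r1 (+2.05) and Nf2 (+1.99) were higher on probe sets that their other probe sets did not follow. Lower were Vwa3a (-2.12, SE 0.421, adjusted p = 0.177), the angiotensin precursor Agt (-2.44, SE 0.54, adjusted p = 0.255), Greb1 (-2.00), Avpr2 (-2.08), Usp31 (-2.14), Tmem243 (-1.53) and Fshb (-1.41). Rbbp6 (-2.52), Dnajc7 (-2.14) and Tmem131 (-2.09) each had at least 1 other probe set of opposite sign. The values for neither colonies are those of the preceding comparison and those for both colonies those of the first, so genes that recur are not separate evidence.

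**Figure D4:**
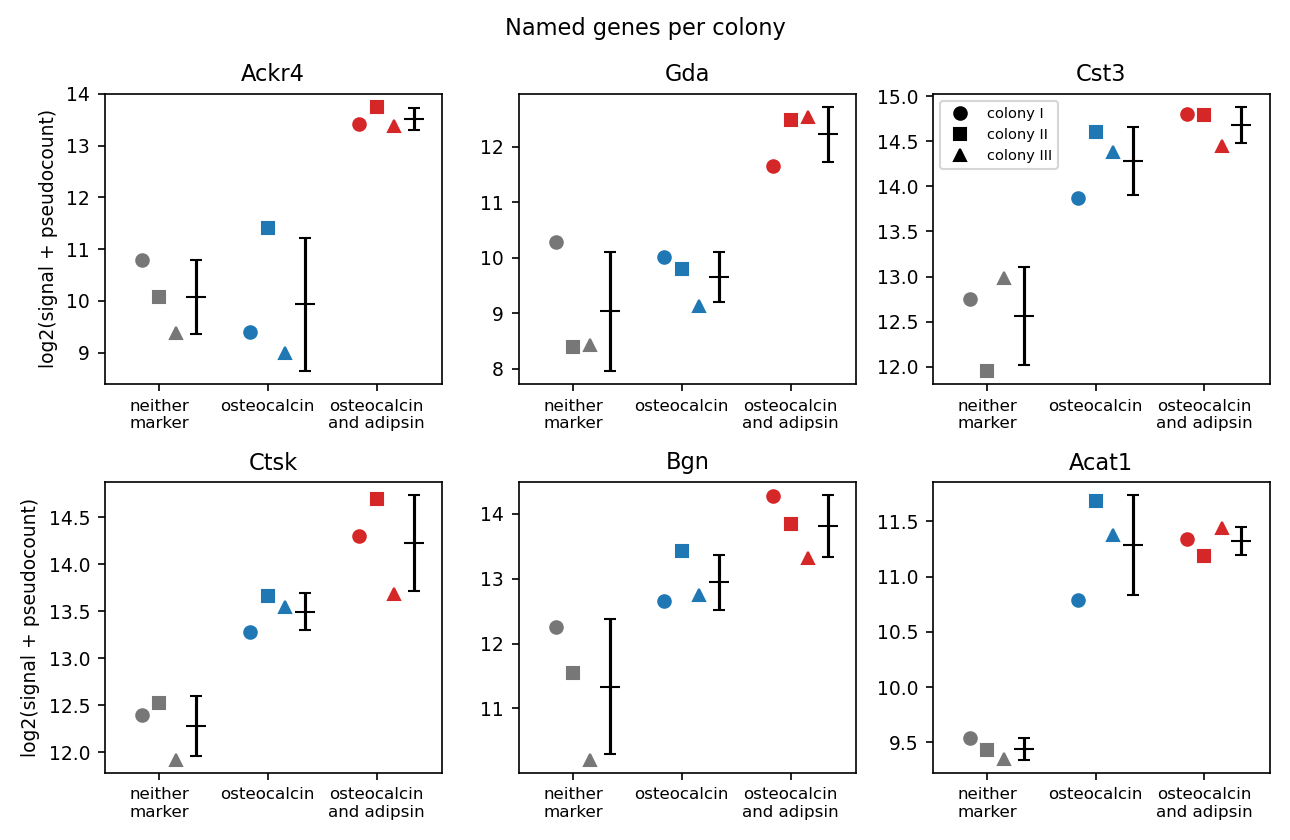
Log2(signal + pseudocount) of 6 genes in each colony, with the mean ± SD of 3 colonies per type beside the points; the vertical axes differ between panels and do not start at 0. Ackr4 and Gda are highest in the both colonies, and Cst3, Ctsk and Acat1 are lowest in the neither colonies.

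Limma called 0 of 19314 probe sets in this comparison as well; 1883 had an unadjusted p under 0.05 (1071 higher, 812 lower; chance 966), and groups did not overlap for 14.6% (chance 10%). With array weights 10 probe sets were called. CameraPR called 0 of 15 lists, and an estimated correlation and fry also called 0; the unadjusted p was under 0.05 for the collagen and matrix list (median +0.32, 31 of 43 higher, p = 0.00914, adjusted p = 0.137) and the glucocorticoid response list (median +0.62, 10 of 13 higher, p = 0.0284, adjusted p = 0.213). Adjusted over the list alone, 3 genes passed limma's test: the matrix proteoglycan Bgn (+2.48, SE 0.486, adjusted p = 0.00925), Ctsk (adjusted p = 0.00125) and the antigen-presentation gene Cd74 (-1.27, SE 0.395, adjusted p = 0.0386); over all genes tested 0 passed. In the glucocorticoid list Tsc22d3 stood at +1.54 (+0.74 without neither III), Mt2A at +2.04 (+0.97 without neither I) and Sgk1 at +0.76 (+0.37 without both III). Osteoblast genes split 8 to 7 (adjusted p = 0.872) with Cthrc1 at +2.91 (SE 0.906), and adipocyte genes 15 to 11 (adjusted p = 0.872) with Cebpd at +1.36 (+0.72 without neither III). Interferon genes had a median of +0.34 (adjusted p = 0.752), with Psmb8 at +1.15 and Bst2 at -1.13, and muscle genes of -0.33 (adjusted p = 0.278). In the BMP, TGF-beta and Wnt list the test statistic opposed the median and mean, and in the stress list the median (-0.02) opposed the mean.

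On chip A only both III shared a station with the neither colonies, so both the fit with station as a block and the values within station 2 set 1 colony against 3. Oxidative phosphorylation was the 1 list called with the block (median +0.54); within station 2 both III differed by +0.54 in that list (41 of 47 higher) and by -0.24 in the collagen and matrix list. Leaving out neither II, in which Gapdh was far below the other colonies, gave 3 probe sets and 2 lists; leaving out neither I gave 1 and 1, and leaving out osteocalcin II gave 1 probe set and leaving out both III gave 2 lists.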

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

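The signals as deposited were the original plan. The rescaling behind the reported values, and the fit without the chip A array of osteocalcin I, were chosen after seeing the data; the other settings were planned. Counts are given in the order both against osteocalcin, osteocalcin against neither, both against neither. Limma called 0, 0 and 0 probe sets and cameraPR 7, 1 and 0 lists. Array weights gave 88 probe sets in the first comparison and 10 in the last, with 4, 3 and 1 lists. In the first comparison the weighted differences of Pla2g2a, Dcn and Fmod were +6.44, +3.51 and +3.02. They lay near the +6.50, +3.72 and +3.48 within station 1 of chip A, a fit without both III. The 88 calls may thus rest largely on the same colonies and are not separate evidence. The weight of each array was not examined. Fitting only the types compared gave 1 probe set in the first and 1 in the last comparison. Adjustment within each chip gave 2 in the first. Without a filter 1 list was called in the last comparison; the stricter filter, quantile normalization and the 3' to 5' ratio each gave 0 lists in the middle one, and the ratio 2 in the last. Station as a block gave 5 lists in the middle and 1 in the last comparison, chip lot 1 in the last. The estimated correlation and fry gave 0 lists in the first and 0 in the middle comparison. Osteocalcin I as deposited gave 1 probe set and 1 list in the first and 0 lists in the middle comparison, and leaving it out of chip A gave 4 lists in the first. The cause of these shifts was not tested.

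Colonies with the same replicate number were not treated as pairs, since the labels do not say whether equal numbers share a preparation. Their deviations gave r from -0.15 to 0.325, and 9 of 18 pairs exceeded 0.1, with each pair of colonies counted on both chips. All 6 pairs numbered I and all 6 numbered III were positive, against 2 of 6 numbered II, so a shared source is not excluded. With the number as a replicate block, 2 probe sets were called in the first comparison and the list counts stayed within 1.5 times. Probe sets with an unadjusted p under 0.05 by limma rose from 654, 1450 and 1883 to 821, 1691 and 2187. Limma's smallest adjusted p fell from 0.327 to 0.113 in the middle comparison and from 0.159 to 0.0775 in the last. Leaving out each colony in turn gave 0 to 1, 0 to 0 and 0 to 3 probe sets and 1 to 7, 0 to 2 and 0 to 2 lists; the lowest list count of the first comparison, 1, came without both II.

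Some called lists changed the sign of their median. In both against osteocalcin the interferon list went to -0.019 with the stricter filter, ribosomal proteins to 0.00787 with quantile normalization and the cell cycle to -0.087 without both II. The cell cycle median was 0.53 without both III and reached 0.87 over all alternatives. With osteocalcin I as deposited, muscle went to 0.14, oxidative phosphorylation to 1.02, ribosomal proteins to 1.25 and stress genes to 0.78, and against neither oxidative phosphorylation to -0.97. That scale moved the chip A median of all genes to 0.859 and -0.895, so these signs follow the array's scale. For the markers, every difference stayed uncalled in every setting run. Of 194 named genes and comparisons, 159 kept their sign in every setting run for them (24, or 23 where the stricter filter removed the probe set) and 28 were called in at least 1. Leaving out 1 colony moved 0 of the 60 genes ranked by p and 78 of 134 list members by over 1.5 times or across 0. The 60 had been picked in these data for a small p and groups that did not overlap. That choice makes such a move unlikely, so the 0 is no evidence that they are stable. A random block for the day was not run, because the other day of chip A held 1 array and the first run of chip B only osteocalcin colonies. Dim signal limits Bglap, which lay no higher than the 5.39 percentile in 8 of 9 colonies.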

Other observations

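The genes of the next paragraph were chosen after their values were seen, and all tests below except the counts over other splits of the colonies were chosen after the result was seen, as were the counts of 1 split per chip and with station as a block.

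Some single transcripts differed widely within types. Pla2g2a, a secreted phospholipase, reached 15.16 log2 units in both I, 14.43 in both II and 11.75 in neither II, and stayed between 8.12 and 8.61 in the other 6 colonies. The growth factor Igf1 was 13.51, 14.32 and 13.42 in those colonies and 9.85 in both III, but also 12.65 in osteocalcin I and 12.32 in osteocalcin III. Dcn was 13.60, 13.79 and 13.11 there and at most 10.49 elsewhere. The smooth muscle actin Actg2 ran from 8.91 in neither I to 15.35 in both III, with 9.46 in both II.

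With 3 colonies against 3 there are 10 splits, too few for a share under 0.05. For both against osteocalcin the real split gave 0 probe sets and the highest other 2 (10 of 10 splits as large), and 7 lists against 7 (2 of 10). At an unadjusted p under 0.05 by limma it gave 654 against 2304 (4 of 10). The split with 2304 set osteocalcin I, both I and both II against osteocalcin II, osteocalcin III and both III. In the other comparisons these counts were 1450 against 1753 and 1883 against 2944 (3 of 10 each). The unadjusted counts were chosen after their values were seen. For osteocalcin against neither the real split gave 0 against 0 (10 of 10) and 1 list against 4 (8 of 10). For both against neither it was 0 against 141 (10 of 10) and 0 lists against 5 (10 of 10). Where the real split gave 0, every split is as large by definition, and the 10 of 10 carries no information. The split with 141 probe sets set both I, both II and neither II against both III, neither I and neither III. It may point to a structure of the samples other than the types, but it was picked as the highest of the other splits. On chip A it follows the stations for 5 of its 6 colonies, all but neither II, but on chip B each side held 2 colonies of station 1 and 1 of station 2, and 64 of the 141 probe sets were on chip B. With station as a block this split gave 195 probe sets (74 on chip A, 121 on chip B), and the real split 0 probe sets and 1 list, on chip A from both III alone against the neither colonies.

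Colonies of one type were not shown to be more alike than colonies of different types. Noise of single hybridizations is argued against, because the 36 correlations between colonies on chip A went with those on chip B (Mantel r = 0.916, exact one-sided permutation p = 2.76e-06, the smallest possible; r = 0.77 without neither III). The Mantel test cannot separate differences between the cells from differences in a colony's RNA or its amplification, which both its arrays may share. Fluidics station as the whole cause is argued against too, because colonies shared stations differently on the 2 chips and the correlations still went together once station was removed on each (Mantel r = 0.712, exact one-sided permutation p = 0.00188; r = 0.60 without neither III); a part from station stays open, since the mean r within stations minus that between them was 0.0227 on chip A (exact one-sided permutation p = 0.103) and -0.00507 on chip B (exact one-sided permutation p = 0.492). A matrix-rich against a contractile state of the cells may underlie the structure as a hypothesis, but the means of the collagen and matrix list and the muscle list gave r = -0.583 over 9 colonies (exact two-sided permutation p = 0.10, adjusted p = 0.233 over 14 relations; rho = -0.561, p = 0.121, adjusted p = 0.242; r = -0.464 without both I and both II), which does not decide it. Of these 14 relations only that with the osteoblast list passed by Pearson's r (r = 0.821, exact two-sided permutation p = 0.00278, adjusted p = 0.0389). By rank rho was 0.815 (exact two-sided permutation p = 0.0104, adjusted p = 0.146), and r was 0.757 without both I and both II. It did not pass with station removed (r = 0.796, exact permutation p = 0.00764, adjusted p = 0.107). The stations hold 5 and 4 colonies, under the 6 required here for a value within each. The osteoblast list itself holds matrix genes such as Col1a1, Col1a2 and Sparc, so this relation may be partly built in.

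Gapdh, a glycolytic enzyme gene, was at a signal of 1270 (3' probe set) on chip A in neither II, where the median of the other 8 colonies was 42200. A fault of one array is argued against, since the gap to the lowest other colony was 3.6 log2 units on chip A and 4.22 on chip B for the 3' probe sets, although only 0.86 and 1.63 for the 5' ones; the log2 3' to 5' ratio was 1.06 on chip A, where the other colonies had 3.11 or more. A lower level of all glycolytic transcripts is argued against as well: 12 other glycolytic genes, some seen before they were listed, deviated by a median of -0.096 (SD 0.726), against -4.80 for Gapdh, although Eno1 stood at -2.10. Loss of some abundant transcripts during amplification is consistent with 12 abundant chip A probe sets lying over 2 log2 units below all other colonies, among them Eif5a, Myh9 and Pfn1, where no other colony had more than 2 (at 1 log2 unit, also looked at, 55 against 27). On chip B the count was 2, so this may hold for part of the pattern, and a low level in the colony itself was not tested.

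Neither III stood apart from the other colonies, most on chip B. Noise near the floor is argued against, because over the brightest 25% of chip B probe sets its mean r was 0.246, where the lowest other colony had 0.505 (0.256 over the brightest 50% and 0.282 over the brightest 10%, also looked at). A different colony on each chip is argued against, because over the 100 shared probe sets its chip A array matched its own chip B array (r = 0.42) better than any other (r = 0.243). A fault of the chip B array stays open: on chip A its mean r was 0.755 over the brightest 25%, within the 0.705 to 0.829 of the others, but below them over all kept probe sets (0.664) and over the brightest 50% (0.706, lowest other 0.733), and within them over the brightest 10% (0.765, others 0.654 to 0.803). On chip B 51 abundant probe sets lay over 2 log2 units below all other colonies, against 4 at most in another colony, and the type of the colony as a biological explanation was not tested.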
